A study of Mus musculus with 16 samples.

How the data were processed

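Gene expression was measured on 16 Agilent mouse arrays with 2 colours, 1 array per sample. Per the labels, 8 arrays carried blood RNA of mice with Hepa1-6 tumours and 8 carried RNA of a tumour fraction enriched in infiltrating inflammatory cells, both in Cy5. Blood RNA of untreated C57Bl/6 mice was in Cy3 on all 16 arrays, and no dyes were swapped. Both groups carry the sample numbers 889, 890, 891, 893, 894, 896, 897 and 898. The labels' protocols state that tumour fractions were isolated by density gradient centrifugation, that blood went into a preservative, and that different RNA kits served the groups. Each of 4 slides held 4 arrays, slides 1 and 2 of blood and slides 3 and 4 of infiltrating cells.

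The deposited scanner files hold the median pixel intensity of each spot and of its local background in both channels, per the file headers written by Agilent Feature Extraction 10.5.1.1. The submitters' processing notes name version 9.1.3.1 of the same program. The same deposited files give a log10 ratio of Cy5 over Cy3, which the program had background-subtracted, detrended and dye-normalised per the file headers. The series' value table was checked against these ratios and differed by 0 on every array. Its medians were 0 on all 16 arrays, and 16.4% to 40.6% of an array's spots had a ratio of exactly 0. Scale and direction of that table therefore followed from the scanner files, and its centring was that of the program. Mean spot intensities had been planned as input, but the files do not hold them and the median intensities were used.

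Background was corrected with normexp (offset 50) and log2 ratios were normalised within each array by loess, in limma 3.58.1 under R 4.3.3, with tables read by the data.table package, version 1.17.8. Of 45018 features, 43379 were not control spots. Control spots had weight 0 in loess, and the 87 to 153 spots per array that carried a non-uniformity or population outlier flag were left out. No spot was saturated. Spots of one probe were averaged, which gave 41174 probes. Probes were named through the RefSeq accession in the files, matched without version to a RefSeq gene table of assembly GRCm38.p6. In this way 23374 probes had 1 symbol, 0 had several and 17800 had none and were not named. The array design was built on an older assembly, so no coordinates are given. A probe was tested if it lay well above background on at least 4 of 8 arrays of either group in Cy5, or on at least 8 of 16 arrays in Cy3, which left 26494 probes. A gene was represented by its probe of highest mean log2 intensity, and 12298 genes were tested. Of 4048 genes with several tested probes, 0 had probes called in opposite directions in blood, 7 in infiltrating cells and 14 in the difference of the groups.

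Ratios of each group were tested against 0 with limma (lmFit and eBayes) on the 8 arrays of that group. Infiltrating cells and blood were compared with limma on all 16 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes together with a change of at least 2-fold. The reference stands for 1 control sample, so the ratio against 0 leaves out the spread between untreated mice, and a dye bias of a gene stays in its ratio. The p-values of single genes measure the spread between these samples. Those of the list tests and of the Fisher exact test below are taken over genes, which are not independent replicates. Values are the mean log2 ratio with limma's standard error (SE). A gene not well above background on any array of one side is given as a bound, which holds for this processing; where the floor left the fitted value as it was (Y-linked genes), no fold is given. The bound divides the bright side's mean by the dim side's mean of, per array, the higher of the probe's signal and the lowest signal among probes well above background. These means are log2 intensities of single channels after loess and scaling between arrays, and stay open to dye bias.

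The report names the 6 largest rises and 6 largest falls per comparison among called genes well above background on at least 4 arrays of each side. These had to move the same way on all 8 arrays, or, for the difference of the groups, to have groups that did not overlap. It also names up to 2 called members of each gene list and 14 genes chosen for the tumour and its cells, of which H19, Hbb-b1 and Mki67 had no named or tested probe. Other list members were chosen as examples after their values were seen, and 3 genes that the rule names are not reported here. The 23 gene lists held 456 genes, of which 29 had no named probe and 400 were tested. They cover neutrophil genes, monocyte and macrophage genes, alternative activation and suppressor genes, T cell genes, regulatory T cell and checkpoint genes, B cell genes, NK and cytotoxic genes, dendritic cell genes and MHC class II genes. Further lists are mast cell, basophil and eosinophil genes, erythroid genes, platelet genes, hepatoma and hepatocyte genes, fibroblast and matrix genes, endothelial genes, interferon-stimulated genes and chemokine genes. The remaining lists are inflammatory cytokine genes, matrix protease genes, cell cycle genes, hypoxia and glycolysis genes, immediate-early and heat-shock genes and Y-linked genes. Ccr7 stands on the T cell and the dendritic cell list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. Camera compares a list with the other genes, and its p-values were adjusted over the lists of a comparison. Missing values were filled with the group mean for camera. The lists, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined.

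The calling steps were tested on simulated ratios of the 12298 genes of each comparison, with known changes at 50 genes per fold in each group. These ratios had independent noise and entered after normalisation. Background correction, loess and the choice of centre were therefore not tested. Changes of 3-fold were called for 100% of genes in blood, 98% in infiltrating cells and 98.0% in the difference, changes of 4-fold and 8-fold for 100%, and changes of 1.5-fold for 0%. Of the unchanged genes 0 were called. The 2-fold limit holds back small changes, so the values for 1.5-fold and for unchanged genes say little about the tests. The precision of each value is limited by the number of arrays.

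The first set of alternatives was no background correction, the deposited ratios, the series' value table, median centring in place of loess, Aquantile scaling, other filters on dim probes, outlier flags ignored and slide as a random block. They also covered the samples of one slide per group, each sample number left out, an intensity trend with robust moderation, one fit over all arrays, the sample number as a block, other thresholds, the mean over a gene's probes and the Cy5 channel alone. Alternatives added after seeing the data were normexp without debris spots (local background over 50 units brighter than the spot), a maximum likelihood fit, subtraction with a floor, infiltrating-cell arrays 897 and 898 left out, and centring on the spike-in controls. No column of other samples was found, and no tested sample was left out of the main comparisons.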

Results

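Blood and a tumour fraction enriched in infiltrating inflammatory cells were profiled from mice that carried subcutaneous tumours of Hepa1-6, a mouse hepatoma cell line. Tissue was taken 10 days after inoculation. The labels describe the mice as athymic in the treatment text and as C57Bl/6 in the strain field, and give female for both channels. Blood (8 samples) and a density gradient fraction enriched in infiltrating cells (8 samples) were each hybridised against blood RNA of untreated mice, called the reference below. The fraction is called infiltrating cells below, but the hepatoma transcript Afp was bright in it, at 67254 to 337814 units in Cy5 against 35.65 to 79.5 in blood. Which cells of the fraction, tumour cells included, carried a change was not tested. In the sample channel, 24.8% to 36.3% of probes were well above background in blood and 51.1% to 65.8% in infiltrating cells, against 41.0% to 51.0% in the reference channel. Across tested probes, ratios correlated at 0.56 to 0.83 between blood arrays, at 0.80 to 0.98 between infiltrating-cell arrays and at −0.31 to −0.08 between the groups (−0.30 to −0.08 over all probes). Genes are not independent replicates, and the direction of each ratio follows the dyes in the labels. Loess sets the middle of each array to 0, so that each value is relative to its array's centre. Centring each array on its median in place of loess (median centring) moved the median of all genes to −0.16 in blood, 1.20 in infiltrating cells and 1.46 in their difference, and centring on the spike-in controls (spike-in centring) moved it to −0.57, 1.91 and 2.50. The deposited ratios had medians of −0.11, 0.17 and 0.42. Values under the centring alternatives were computed for lists, for genes named by rule and for genes called in both groups; falls of other genes smaller than these shifts can reverse under them.

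The ratio of blood against the reference addresses how circulating cells of tumour-bearing mice differed from untreated blood. Gabarapl2, which encodes a protein of autophagosome formation, rose by 2.85 ± 0.05 log2 (SE, n = 8; limma adjusted p = 2.0e-14). Cxcr2, the neutrophil receptor for several CXC chemokines, rose by 2.24 ± 0.11 (n = 8; limma adjusted p = 8.8e-10), and Hp, which encodes haptoglobin, a binder of free haemoglobin, by 2.06 ± 0.06. Cd79b, a signalling chain of the B cell receptor, fell by 1.54 ± 0.11 (n = 8; limma adjusted p = 4.3e-08), and Ms4a1, which encodes the B cell surface protein CD20, fell by 1.35 ± 0.13. Each of these moved the same way on all 8 arrays.

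The other large rises were Cd82, a tetraspanin (2.19 ± 0.05), Aldh2, a mitochondrial aldehyde dehydrogenase (1.94 ± 0.06), and Swi5, a homologous recombination factor (1.88 ± 0.04). The other large falls were Blnk, an adaptor of the B cell receptor (−1.29 ± 0.11), Ly6d, a surface protein of B lineage cells (−1.28 ± 0.09), Cirbp, a cold-inducible RNA-binding protein (−1.28 ± 0.06), and Tnfrsf13c, the BAFF receptor of B cells (−1.22 ± 0.09). Of 12298 genes tested, 62 rose and 30 fell, 92 in all. The counts of list members that follow were identical when p-values were adjusted over the list alone.

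**Figure D1:**
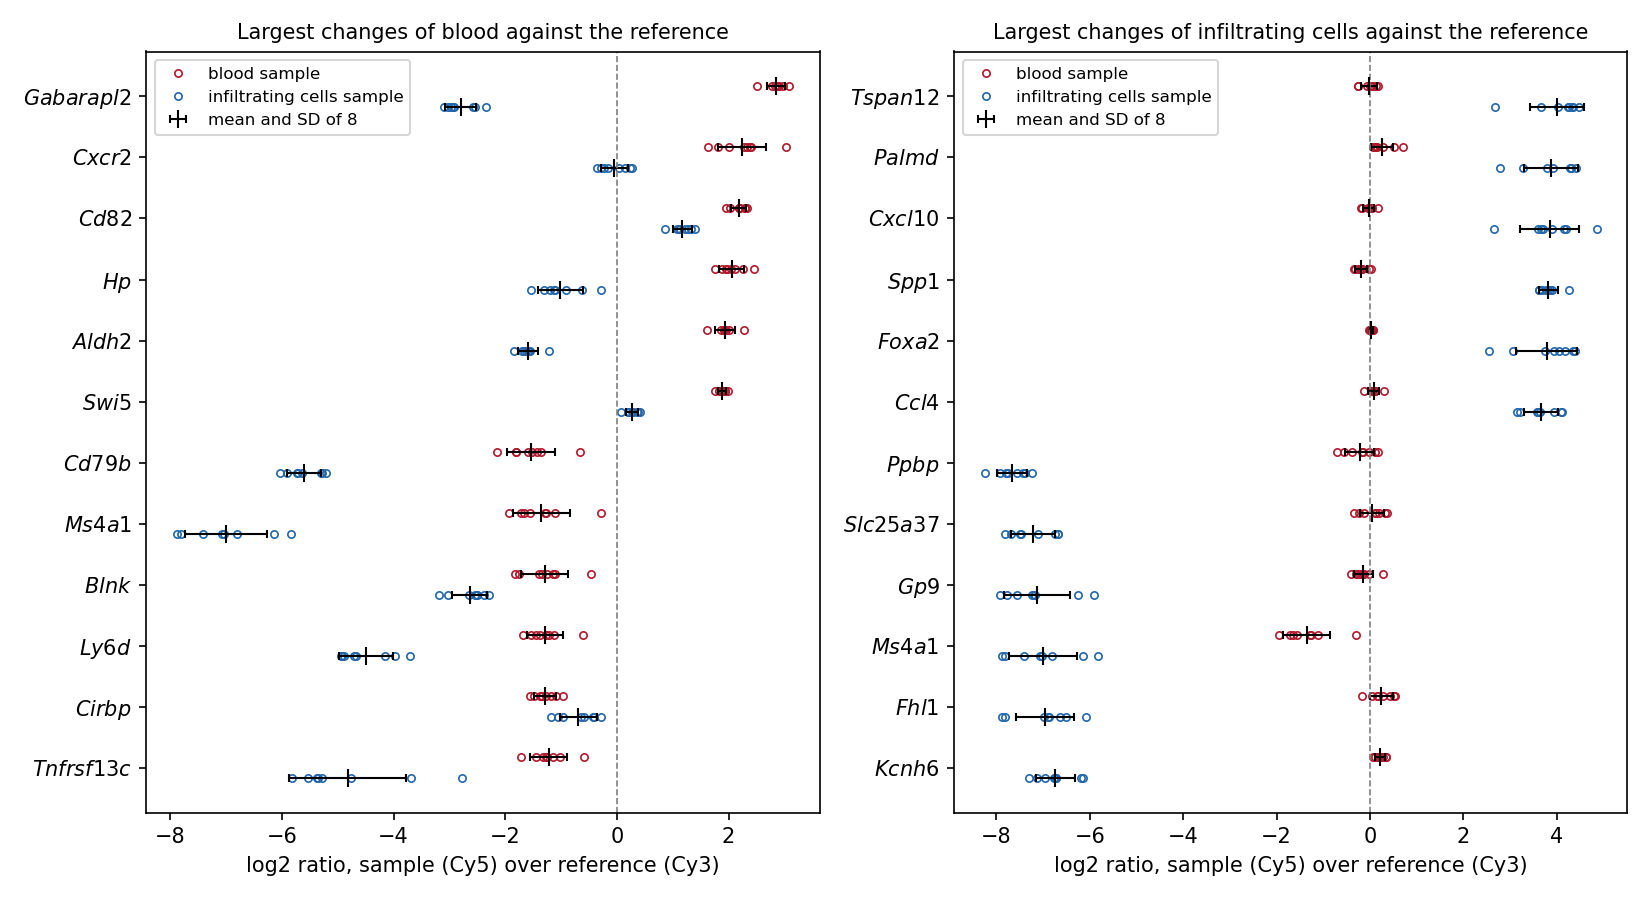
Log2 ratio of sample over reference for the genes with the largest changes, 6 up and 6 down, in blood (left) and in infiltrating cells (right), 1 open circle per sample, with the mean and SD of 8. Gabarapl2 had a mean of 2.85 in blood and −2.80 in infiltrating cells, and Ppbp a mean of −7.67 in infiltrating cells.

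Genes of neutrophils rose in blood, with 5 of 14 measured members higher, 0 lower and 9 not called. Beside Cxcr2 these included Il1r2, a decoy receptor for interleukin 1 (1.27), and S100a8, a calcium-binding alarmin (1.11 ± 0.12), which was 0.995 and lost its call without sample 898. Its partner S100a9, at 0.93 ± 0.12, was not called, but reached 1.06 without sample 896. The median of the neutrophil genes was 0.54, 0.25 with median centring and −0.02 with spike-in centring (camera adjusted p = 2.1e-05; adjusted p = 0.352 with an estimated correlation). Among B cell genes 6 of 18 fell, 0 rose and 12 were not called, with Fcrla (−1.22) and Fcmr, an IgM receptor (−1.17), beside Cd79b, Ms4a1, Blnk and Tnfrsf13c, and a median of −0.82 (camera adjusted p = 2.8e-08; adjusted p = 0.352 with an estimated correlation). The MHC class II genes, which present antigen on B cells and myeloid cells, had a median of −0.53 with 0 of 9 members called (camera adjusted p = 6.4e-05; adjusted p = 0.352 with an estimated correlation).

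Erythroid genes had a median of 0.47, 0.01 with median centring and −0.08 with spike-in centring, with 1 of 25 members higher, 0 lower and 24 not called (camera adjusted p = 1.2e-09; adjusted p = 0.0756 with an estimated correlation). The 15 platelet genes held 4 higher members, 0 lower and 11 not called, among them Itga2b, a subunit of the platelet fibrinogen receptor (1.45), and F13a1, which encodes a subunit of coagulation factor XIII (1.24). Their median was 0.18, −0.47 with median centring and −0.37 with spike-in centring (camera adjusted p = 0.0288; adjusted p = 0.416 with an estimated correlation), and without sample 891 the adjusted p was 0.0751 (5.5e-05 to 0.416 over 27 alternatives).

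Interferon-stimulated genes had 2 members of 23 higher, 0 lower and 21 not called, namely Isg15, a ubiquitin-like modifier (1.61), and Oasl2 (1.33). Their median was 0.11, −0.29 with median centring and −0.44 with spike-in centring (camera adjusted p = 0.00665; adjusted p = 0.352 with an estimated correlation). Of 19 NK and cytotoxic genes 1 rose and 18 were not called. It was Tbx21, which encodes the transcription factor T-bet (1.13), and the list median was 0.17, or −0.38 with spike-in centring (camera adjusted p = 6.4e-05; adjusted p = 0.0756 with an estimated correlation). Among 15 inflammatory cytokine genes Il1b, which encodes interleukin 1 beta, rose by 1.34 ± 0.09 and 14 were not called. That list had a median of 0.06, or −0.49 with spike-in centring (camera adjusted p = 0.0356; adjusted p = 0.352 with an estimated correlation), and its adjusted p was 0.0543 without sample 898 (0.0004 to 0.352 over 27 alternatives). Of the 3 Y-linked genes tested, Eif2s3y and Ddx3y were called lower, both not well above background in Cy5 on any blood array, so that no fold is given. Their fitted values were −1.79 (−5.51 to −1.15 over 25 alternatives) and −1.03 (−4.33 to −0.57), and Ddx3y lost its call without sample 896 (−0.98) or without sample 897 (−0.9996). The Y-linked genes had a median of −1.03 (camera adjusted p = 0.00342; adjusted p = 0.352 with an estimated correlation), and the labels give female for both channels.

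T cell genes of blood lay near the reference. Of 19 tested, 0 were called, the median was −0.09 (camera adjusted p = 0.102), and Cd3e, a chain of the T cell receptor complex, was at 0.44 ± 0.05. With median centring the median was −0.66 and the list was called (camera adjusted p = 0.00896; 0.00896 to 0.445 over 27 alternatives). Single members were called in lists that did not pass the test. Ctss, a lysosomal protease of antigen-presenting cells, fell by 1.07 as the 1 called of 21 monocyte and macrophage genes (median −0.11, camera adjusted p = 0.244). Zbtb46, a transcription factor of dendritic cells and of erythroid progenitors, rose by 1.19 as the 1 called of 13 dendritic cell genes (median 0.00, camera adjusted p = 0.997). Hdc, the enzyme that makes histamine, rose by 1.77 as the 1 called of 12 mast cell, basophil and eosinophil genes (median 0.07, camera adjusted p = 0.0813).

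Adam8, a membrane protease, rose by 1.37 as the 1 called of 23 matrix protease genes (median 0.02, camera adjusted p = 0.172). Slc16a3, a lactate exporter, rose by 1.02 as the 1 called of 24 hypoxia and glycolysis genes, whose median of −0.03 and test, which pointed up, differed in sign (camera adjusted p = 0.633). Its call was lost without sample 890 (0.95), 897 (0.96) or 898 (0.93). Among 22 immediate-early and heat-shock genes Dusp1, a phosphatase of MAP kinases, rose by 1.27 and Klf4 fell by 1.01 (median 0.05, camera adjusted p = 0.214). The call of Klf4 was lost without sample 890 (−0.98), 891 (−0.99), 894 (−0.98), 896 (−0.99) or 898 (−0.98). In 7 further lists 0 members were called. The median was 0.04 for 17 alternative activation and suppressor genes (camera adjusted p = 0.16), 0.01 for 14 regulatory T cell and checkpoint genes (0.946), 0.07 for 15 hepatoma and hepatocyte genes (0.18) and 0.11 for 11 endothelial genes (0.0813). It was −0.03 for 20 fibroblast and matrix genes (camera adjusted p = 0.893), 0.03 for 20 chemokine genes (0.16) and −0.02 for 29 cell cycle genes (0.429). The regulatory T cell test and mean pointed down, and the fibroblast and cell cycle tests pointed up, against their medians. Afp was at −0.24, Csf1r at −0.15 and Ncr1 at −0.09, all not called. Cxcl10, Alb and Arg1 were not called either, and no ratio is given because their Cy5 signal was not well above background on any blood array.

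The calls in blood depended on the centring. Median centring called 894 genes, 10 higher and 884 lower, spike-in centring 673, 13 higher and 660 lower, and the deposited ratios 956, 326 higher and 630 lower, against 67.4% higher among the 92. Of the rises named above, these lost their call with median and with spike-in centring: Il1r2 (0.86 and 0.72), S100a8 (0.54 and 0.56), Itga2b (0.79 and 0.89), F13a1 (0.58 and 0.69), Oasl2 (0.67 and 0.78), Tbx21 (0.56 and 0.58), Il1b (0.70 and 0.79), Zbtb46 (0.54 and 0.64), Adam8 (0.73 and 0.82), Slc16a3 (0.42 and 0.46) and Dusp1 (0.62 and 0.72). Isg15 lost it with median centring alone (0.97). Without background correction Il1r2 (0.79), Tbx21 (0.80) and Slc16a3 (0.74) were not called and S100a9 was (1.08), and in the samples of the first slide Ctss (−0.81), Tbx21 (0.86) and Slc16a3 (0.87) were not called and S100a9 was (1.12). The 4 samples of the first slide called 61 genes and those of the second slide 152.

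The ratio of infiltrating cells against the reference addresses how the tumour fraction, as isolated by density gradient, differed from untreated blood. Effects of the isolation on transcripts were not separated from differences of the cells. Tspan12, a tetraspanin, rose by 4.01 ± 0.18 log2 (SE, n = 8; limma adjusted p = 3.5e-08), and Cxcl10, which attracts activated T cells, by 3.85 ± 0.19 (n = 8; limma adjusted p = 7.6e-08). Spp1, which encodes the secreted glycoprotein osteopontin, rose by 3.82 ± 0.07, and Ccl4, a chemokine for monocytes and T cells, by 3.67 ± 0.11. Ppbp, the platelet basic protein, fell by 7.67 ± 0.10 (n = 8; limma adjusted p = 3.3e-11), and Slc25a37, the mitochondrial iron importer of erythroid cells, fell by 7.22 ± 0.14. All moved the same way on 8 of 8 arrays.

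The other large rises were Palmd (3.88 ± 0.18) and Foxa2, a transcription factor of liver and endoderm (3.78 ± 0.20). The other large falls were Gp9, a subunit of the platelet receptor for von Willebrand factor (−7.13 ± 0.21), Ms4a1 (−7.00 ± 0.22), Fhl1 (−6.96 ± 0.19) and Kcnh6, a potassium channel (−6.74 ± 0.13). In all, 1147 genes rose and 1245 fell, 2392 of 12298. Counts of list members were again identical when adjusted over the list alone.

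Transcripts of red cells and platelets fell most. Of 25 erythroid genes 21 fell and 4 were not called, among them Fech, the last enzyme of haem synthesis (−6.45), and Slc4a1, the anion exchanger of the red cell membrane (−6.36). Their median was −4.42 (camera adjusted p = 1.9e-10; adjusted p = 0.201 with an estimated correlation). Of 15 platelet genes 12 fell and 3 were not called, with a median of −4.55 (camera adjusted p = 4.4e-07; adjusted p = 0.29 with an estimated correlation). B cell genes fell in 17 of 18 cases and 1 was not called, with Cd79b at −5.60 and a median of −3.16 (camera adjusted p = 3.0e-08; adjusted p = 0.35 with an estimated correlation). Vwf, von Willebrand factor of endothelium and platelets, fell by 5.30 as the 1 called of 11 endothelial genes, whose median was −0.21, or 0.18 with median centring and 1.65 with spike-in centring (camera adjusted p = 0.0802).

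Of 14 neutrophil genes 4 fell and 10 were not called, with S100a9 at −3.00 ± 0.17 and S100a8 at −2.85 ± 0.18. With median centring both lost their call (−0.73 and −0.76), and with spike-in centring S100a8 did (−0.98; S100a9 −1.13). The list's median was −0.34, 0.17 with median centring and 1.52 with spike-in centring (camera adjusted p = 0.0224; adjusted p = 0.41 with an estimated correlation). MHC class II genes fell in 5 of 9 cases and 4 were not called. H2-Oa, a regulator of peptide loading, was at −3.10, and H2-Ab1, a chain of the class II molecule, at −1.67, but at 0.56 with median centring and 0.19 with spike-in centring. The list median was −1.01, 0.78 with median centring and 0.86 with spike-in centring (camera adjusted p = 0.000279; adjusted p = 0.201 with an estimated correlation).

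Monocyte and macrophage genes rose in 9 of 21 cases, fell in 2 and were not called in 10. Mrc1, the mannose receptor, rose by 2.74 ± 0.15, and C1qc, a chain of complement C1q, by 1.36, whereas Lyz2, a lysozyme of myeloid cells, fell by 1.68 and Csf1r, the receptor for macrophage growth factor, was at −0.05 and not called (2.002 with median centring, 1.82 with spike-in centring). The list median was 0.50 (camera adjusted p = 0.0412; adjusted p = 0.35 with an estimated correlation). Among 17 alternative activation and suppressor genes 5 rose, 1 fell and 11 were not called (median 0.57, camera adjusted p = 0.0549). Besides Spp1, Ido1, which degrades tryptophan, rose by 2.07 and Cd36, a scavenger receptor also of platelets, fell by 3.12, while Arg1, arginase of the liver and of myeloid cells, was at 0.76 ± 0.10 and not called, or 2.94 and called with median centring and 2.62 and called with spike-in centring. The list test was called without sample 890 (adjusted p = 0.0468), 891 (0.0487) or 893 (0.0418), with a range of 0.0192 to 0.916 over 27 alternatives. In these samples erythroid transcripts fell and the hepatoma transcript Afp rose.

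Chemokine genes rose in 14 of 20 cases, 1 fell and 5 were not called. Ccl8 rose by 2.63, Cxcl9 by 2.24 and Ccl2 by 2.19, all attractants of leukocytes, whereas Ccl19, which guides T cells to lymph nodes, fell by 1.05, a call lost without sample 891 (−0.93), 893 (−0.93), 894 (−0.98) or 896 (−0.94). Their median was 1.65 (camera adjusted p = 5.7e-05; adjusted p = 0.209 with an estimated correlation). Among 15 inflammatory cytokine genes Il33 rose by 1.34 and Il1b by 1.01 ± 0.14, and 13 were not called (median 0.15, camera adjusted p = 0.284). The call of Il1b was lost without sample 889 (0.94), 896 (0.996), 897 (0.94) or 898 (0.97), in the samples of the first slide (0.89), in the deposited ratios (0.97), without debris spots (0.98) and with subtraction and a floor (0.98). Interferon-stimulated genes split, with 4 higher, 7 lower and 12 not called. Gbp3, a guanylate-binding protein, rose by 2.34, and Rsad2, the antiviral protein viperin, fell by 6.51. The median of this list was 0.33 and its mean −0.25, while the test pointed up (camera adjusted p = 0.763).

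T cell genes fell in 7 of 19 cases, 0 rose and 12 were not called. Ccr7, the lymph node homing receptor of naive T cells, was at −2.53, or −0.88 and −0.66 and not called with median and spike-in centring. Lef1, a transcription factor of naive T cells, was at −1.66, or −0.66 and not called with median centring and 0.21 with spike-in centring. Cd3e was at −0.74 ± 0.13 and not called, or 1.12 and called with spike-in centring and −1.53 and called in the deposited ratios. The list median was −0.49, 0.81 with median centring and 1.37 with spike-in centring (camera adjusted p = 0.00376; adjusted p = 0.399 with an estimated correlation). Regulatory T cell and checkpoint genes rose in 5 of 14 cases, 1 fell and 8 were not called. Pdcd1, which encodes the inhibitory receptor PD-1, rose by 1.64 and Tnfrsf4, the costimulatory receptor OX40, by 1.33, whereas Btla, an inhibitory receptor of lymphocytes, fell by 3.12. Their median was 0.47 (camera adjusted p = 0.0224; adjusted p = 0.35 with an estimated correlation). Of 19 NK and cytotoxic genes 6 rose, 1 fell and 12 were not called (median 0.47, camera adjusted p = 0.0756). Gzmb, the cytotoxic protease granzyme B, rose by 2.26 ± 0.06 and Il2rb, a chain of the interleukin 2 receptor, by 1.46. Ncr1, an activating receptor of NK cells, was at −0.11 and not called, or 1.75 and called with spike-in centring. Of 13 dendritic cell genes 2 rose, 2 fell and 9 were not called, with Clec10a at 2.02 and Itgax at 1.37. Their median was 0.18, their mean −0.06 and the test pointed up (camera adjusted p = 0.371). Hdc fell by 1.16 as the 1 called of 12 mast cell, basophil and eosinophil genes (median 0.16, camera adjusted p = 0.674), but stood at 0.90 with median centring and 0.70 with spike-in centring.

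Hepatoma and hepatocyte genes rose in 6 of 15 cases and 9 were not called. Afp, the fetal liver protein alpha-fetoprotein, rose by 2.95 ± 0.09, Rbp4, the plasma carrier of retinol, by 1.72 and Alb, serum albumin, by 1.12 ± 0.11 (0.96 and not called in the samples of the first slide). The list median was 0.67 (camera adjusted p = 0.00376; adjusted p = 0.391 with an estimated correlation). The reference channel of these arrays was itself brighter than that of the blood arrays, by 3.46 log2 for Afp, and Rbp4, Alb and Arg1 were well above background in it on 8 of 8 of these arrays and 0 of 8 blood arrays. Fibroblast and matrix genes rose in 3 of 20 cases, fell in 1 and were not called in 16 (median 0.22, camera adjusted p = 0.229). Dcn, a proteoglycan of connective tissue, rose by 2.29 and Sparc, a matrix glycoprotein, by 1.59. Matrix protease genes rose in 8 of 23 cases and 15 were not called, with Ctsl, a lysosomal cysteine protease, at 3.60 ± 0.07 and Mmp14, a membrane metalloprotease, at 3.104. Their median was 0.24 (camera adjusted p = 0.0067; adjusted p = 0.201 with an estimated correlation).

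Hypoxia and glycolysis genes rose in 12 of 24 cases, 1 fell and 11 were not called. Bnip3, a mitophagy receptor induced by hypoxia, rose by 3.40 ± 0.17 and Pgam1, a glycolytic enzyme, by 3.25 ± 0.05, while Pdk1, an inhibitor of pyruvate oxidation, fell by 1.82. Their median was 1.03 (camera adjusted p = 0.00035; adjusted p = 0.209 with an estimated correlation). Immediate-early and heat-shock genes rose in 12 of 22 cases and 10 were not called. Fos rose by 3.25 and Egr2 by 2.90, both transcription factors induced within minutes of stimulation, and the median was 1.12 (camera adjusted p = 0.000724; adjusted p = 0.209 with an estimated correlation). Cell cycle genes rose in 12 of 29 cases, 2 fell and 15 were not called. Cenpe, a kinetochore motor, rose by 2.31 and Mcm6, a subunit of the replicative helicase, by 1.81, while Ube2c fell by 3.06 and Nusap1 by 3.68, both acting in mitosis. Their median was 0.88 (camera adjusted p = 0.00797; adjusted p = 0.35 with an estimated correlation). Of the Y-linked genes, Eif2s3y and Ddx3y were called lower, again without a fold because Cy5 was not well above background on any array. Their fitted values were −3.25 (−9.14 to −1.38 over 25 alternatives) and −2.24 (−7.72 to −0.37). The median of the 3 Y-linked genes was −2.24 (camera adjusted p = 0.0549), and the list was called without sample 897 (adjusted p = 0.0428) or 898 (0.0461), with a range of 0.000436 to 0.399 over 26 alternatives.

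**Figure D2:**
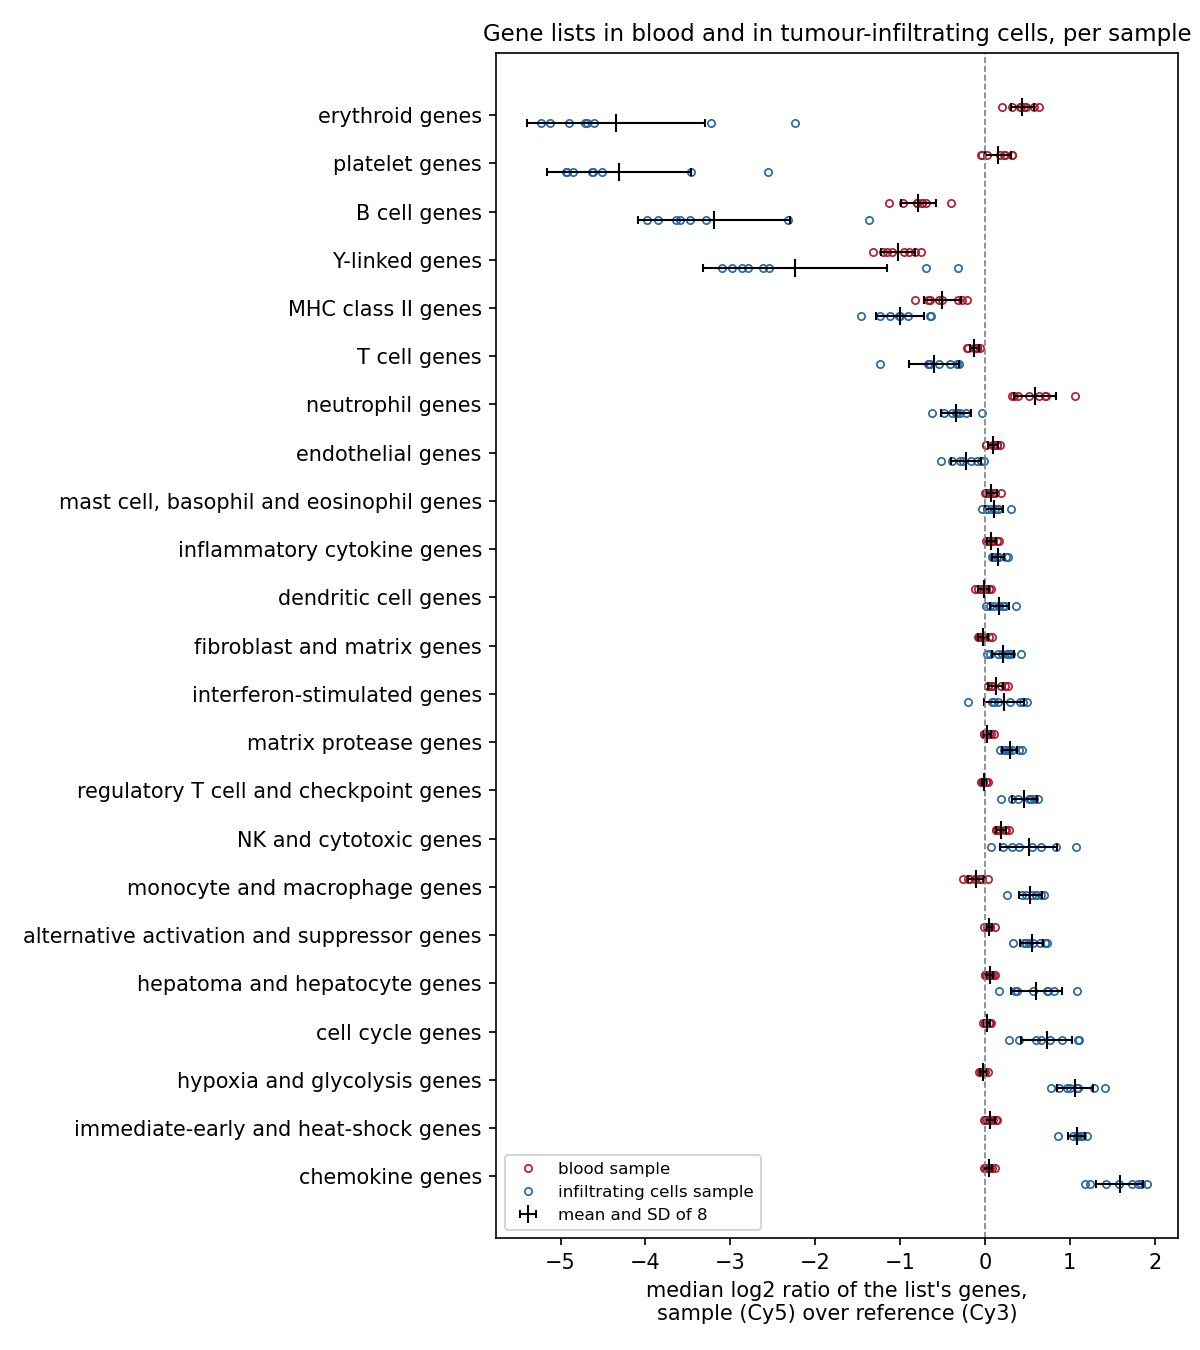
Median log2 ratio of each list's genes over the reference, 1 open circle per sample (red blood, blue infiltrating cells), with the mean and SD of 8. Over the group means, erythroid genes had a median of 0.47 in blood and −4.42 in infiltrating cells and chemokine genes 0.03 and 1.65; with spike-in centring the erythroid median in blood was −0.08.

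Median centring called 7260 genes, 6853 higher and 407 lower, spike-in centring 11087, 97.7% of them higher, and the deposited ratios 5759, 3171 higher and 2588 lower, against 48.0% higher among the 2392. Infiltrating-cell arrays 897 and 898 had a 10th percentile of corrected Cy5 intensity of 561 and 777 units and correlated at 0.80 to 0.91 with the other 6 arrays (0.94 to 0.98 without debris spots), and without them 2823 genes were called, Il1b stood at 0.88 and monocyte and macrophage genes had an adjusted p of 0.0557 (0.00723 to 0.661 over 27 alternatives).

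The direct comparison of infiltrating cells with blood addresses which genes set the tumour fraction apart from the circulation of tumour-bearing mice. The groups also differed in isolation, preservative, RNA kit and slides, so cell content and handling cannot be told apart in it. Ctsl was higher in infiltrating cells by 3.74 ± 0.09 log2 (SE, n = 8 and 8; limma adjusted p = 1.1e-16), and Scd2, a fatty acid desaturase, by 3.73 ± 0.09 (n = 8 and 8; limma adjusted p = 2.0e-16). Pgam1 was higher by 3.52 ± 0.07 and Adamdec1, a metalloprotease of macrophages and dendritic cells, by 3.48 ± 0.24. Ppbp was lower (−7.45 ± 0.15, n = 8 and 8; limma adjusted p = 9.1e-18), as was Slc25a37 (−7.26 ± 0.17). In each case the groups did not overlap.

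Palmd (3.63) and Ccl4 (3.58) were the other large rises, and Fhl1 (−7.20), Gp9 (−6.98), Kcnh6 (−6.95) and Tspo2, an erythroid cholesterol-binding protein (−6.94), the other large falls. In all, 1485 genes were higher and 1450 lower in infiltrating cells, 2935 of 12298. Counts of list members were identical when adjusted over the list alone. Bounds below compare the Cy5 channels, for genes not well above background in blood.

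Erythroid genes were lower in 22 of 25 cases and not called in 3, with Ank1, which anchors the red cell skeleton, at −6.51, Hba-a1, an alpha globin, at −6.48 (−3.94 in Cy5 alone) and a median of −4.98 (camera adjusted p = 5.1e-13; adjusted p = 0.0943 with an estimated correlation). Platelet genes were lower in 14 of 15 cases, 1 was not called and the median was −4.74 (camera adjusted p = 1.1e-09; adjusted p = 0.218 with an estimated correlation). B cell genes were lower in 17 of 18 cases and 1 was not called. Ms4a1 was at −5.65 (−3.05 with median centring, −3.23 with spike-in centring) and Fcmr at −4.31 (−1.73 and −1.89), with a median of −2.48, or −0.70 and −0.06 (camera adjusted p = 2.7e-07; adjusted p = 0.31 with an estimated correlation). Of 11 endothelial genes Vwf (−5.48) and Esam, a junction protein also of platelets (−1.18), were lower and 9 were not called. Esam was at −0.92 and not called without background correction and stood at 0.96 with median centring and 1.23 with spike-in centring, and the list median of −0.22 at 0.13 and 2.20 (camera adjusted p = 0.0413; adjusted p = 0.378 with an estimated correlation). Without sample 889 or 894 the endothelial list had an adjusted p of 0.0501 and 0.0516 (0.0193 to 0.378 over 28 alternatives).

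Neutrophil genes were lower in 7 of 14 cases and not called in 7. S100a8 was at −3.96 ± 0.23 and S100a9 at −3.93 ± 0.23, and the median was −0.93, −0.06 with median centring and 1.49 with spike-in centring (camera adjusted p = 0.000458; adjusted p = 0.3 with an estimated correlation). Monocyte and macrophage genes were higher in 7 of 21 cases, lower in 2 and not called in 12. Ctss was higher by 3.12 and Mrc1 by 2.78, with Csf1r at 0.10 and not called (2.78 with median centring and 2.52 with spike-in centring, both called), and a median of 0.66 (camera adjusted p = 0.0286; adjusted p = 0.31 with an estimated correlation). Among 17 alternative activation and suppressor genes 4 were higher, 1 lower and 12 not called, with Spp1 at 3.999 ± 0.08, Ido1 at least 7.81-fold higher and a median of 0.54 (camera adjusted p = 0.181). Arg1 had a ratio difference of 0.75 ± 0.11 and was not called (2.87 with median centring and 3.16 with spike-in centring, both called), whereas its Cy5 signal alone was at least 35.5-fold higher. The groups also differed in erythroid, platelet and hepatoma transcripts.

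T cell genes were lower in 6 of 19 cases and not called in 13. Ccr7 was at −2.04 (0.28 with median centring, 0.37 with spike-in centring), Lef1 at −1.60 (−0.11 and 0.82) and Cd3e at −1.19 ± 0.15 (0.17 and 1.23, and −0.88 and not called without background correction). The list median was −0.32, 1.46 with median centring and 2.10 with spike-in centring (camera adjusted p = 0.0286; adjusted p = 0.481 with an estimated correlation). Regulatory T cell and checkpoint genes were higher in 6 of 14 cases, lower in 1 and not called in 7. Pdcd1 was at least 11.2-fold higher, Havcr2, which encodes the inhibitory receptor TIM-3, was at 1.36 and the median was 0.54 (camera adjusted p = 0.0413; adjusted p = 0.31 with an estimated correlation). Without sample 889 the adjusted p was 0.0501 for this list, for cell cycle genes and for matrix protease genes (over 28 alternatives 0.00971 to 0.738, 0.00113 to 0.372 and 0.00679 to 0.511). Of 19 NK and cytotoxic genes 2 were higher, 1 lower and 16 not called, with a median of 0.31 (camera adjusted p = 0.547). Gzmb was at 1.48 (3.52 in Cy5 alone, 0.84 and not called in the deposited ratios) and Klrd1, a receptor chain of NK cells, at 1.13 (0.69 in Cy5 alone and 0.72 in the samples of the second slide, not called in either). Ncr1 was at −0.02 and not called, or 2.40 and called with spike-in centring.

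Of 13 dendritic cell genes 4 were higher, 2 lower and 7 not called, with Clec10a at 2.35, Itgax at 1.29 and a median of 0.17, against a mean of −0.05 and a test that pointed up (camera adjusted p = 0.589). MHC class II genes were lower in 3 of 9 cases and not called in 6, with a median of −0.63, 1.91 with median centring and 1.79 with spike-in centring (camera adjusted p = 0.0669; 0.041 without sample 897 and 0.0325 to 0.864 over 28 alternatives). H2-Oa was at −2.37 (0.09 with median centring, 0.05 with spike-in centring) and H2-DMb2 at −1.36 (−0.11 and 1.06, and −0.89 and not called in the samples of the second slide). Hdc was lower (−2.94, or −0.22 and −0.52 and not called with median and spike-in centring) as the 1 called of 12 mast cell, basophil and eosinophil genes, whose median of 0.11 opposed their mean of −0.10 and the test (camera adjusted p = 0.815). Chemokine genes were higher in 13 of 20 cases, lower in 1 and not called in 6. Cxcl10 was at least 30.6-fold and Ccl8 at least 50.6-fold higher, and the median was 1.63 (camera adjusted p = 0.000201; adjusted p = 0.218 with an estimated correlation). Interferon-stimulated genes were higher in 5 of 23 cases, lower in 8 and not called in 10, with Rsad2 at −6.55, Isg20, an exonuclease, at −6.22 and a median of −0.11, or 1.73 with median centring and 2.30 with spike-in centring (camera adjusted p = 0.613). Among 15 inflammatory cytokine genes 1 was higher (Il33, 1.28), 1 lower (Il27, −1.03) and 13 not called. Il27 stood at −0.12 with median centring and 1.38 with spike-in centring, and lost its call without background correction (−0.70), in the samples of the first slide (−0.95) and without sample 894 (−0.95) or 896 (−0.99). The median of that list was 0.04 and its mean 0.03 while the test pointed down (camera adjusted p = 0.815), and Il1b was at −0.34 ± 0.18 and not called, or 2.44 and 2.08 and called with median and spike-in centring.

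Hepatoma and hepatocyte genes were higher in 5 of 15 cases and not called in 10. Afp was higher by 3.19 ± 0.10, Alb at least 322-fold and Rbp4 at least 349.6-fold, although the ratio differences of Alb and Rbp4 were 1.13 (0.99 and not called in the samples of the first slide) and 1.80. The Cy5 signal alone of Afp differed by 8.20, and Alb and Rbp4 were well above background in the reference channel on infiltrating-cell arrays and not on blood arrays, so that the reference did not cancel for these genes and the ratios understate the Cy5 difference. The list median was 0.46 (camera adjusted p = 0.0286; adjusted p = 0.437 with an estimated correlation). Fibroblast and matrix genes were higher in 3 of 20 cases, lower in 2 and not called in 15, with Dcn at 2.15 (7.56 in Cy5 alone, 4.63 with median centring and 4.56 with spike-in centring), Sparc at least 7.86-fold higher and a median of 0.23 (camera adjusted p = 0.458). Matrix protease genes were higher in 7 of 23 cases, lower in 1 and not called in 15. Mmp14 was at least 21.5-fold higher, Mmp9, a gelatinase of neutrophils, was at −1.34, and the median was 0.23 (camera adjusted p = 0.0413; adjusted p = 0.3 with an estimated correlation).

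Hypoxia and glycolysis genes were higher in 13 of 24 cases, lower in 2 and not called in 9, with Bnip3 at 3.25, Ldha, lactate dehydrogenase, at 2.87 and a median of 1.18 (camera adjusted p = 0.00402; adjusted p = 0.218 with an estimated correlation). Immediate-early and heat-shock genes were higher in 12 of 22 cases, lower in 1 and not called in 9, with Egr2 at 2.82, Klf4 at 2.75 and a median of 1.06 (camera adjusted p = 0.0111; adjusted p = 0.3 with an estimated correlation). Cell cycle genes were higher in 11 of 29 cases, lower in 3 and not called in 15, with Mcm6 at 2.37, Cenpe at 2.01 and a median of 0.91 (camera adjusted p = 0.0364; adjusted p = 0.372 with an estimated correlation). Of 3 Y-linked genes Eif2s3y (−1.46) and Ddx3y (−1.21) were called lower. Neither was well above background in Cy5 in either group, so no fold is given. With median centring they stood at −0.14 and −0.40 and were not called, and with spike-in centring at 0.96 and 1.20. In Cy5 alone they stood at −0.09 and −0.18. The list median was −1.21, or 1.20 with spike-in centring (camera adjusted p = 0.333).

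**Figure D3:**
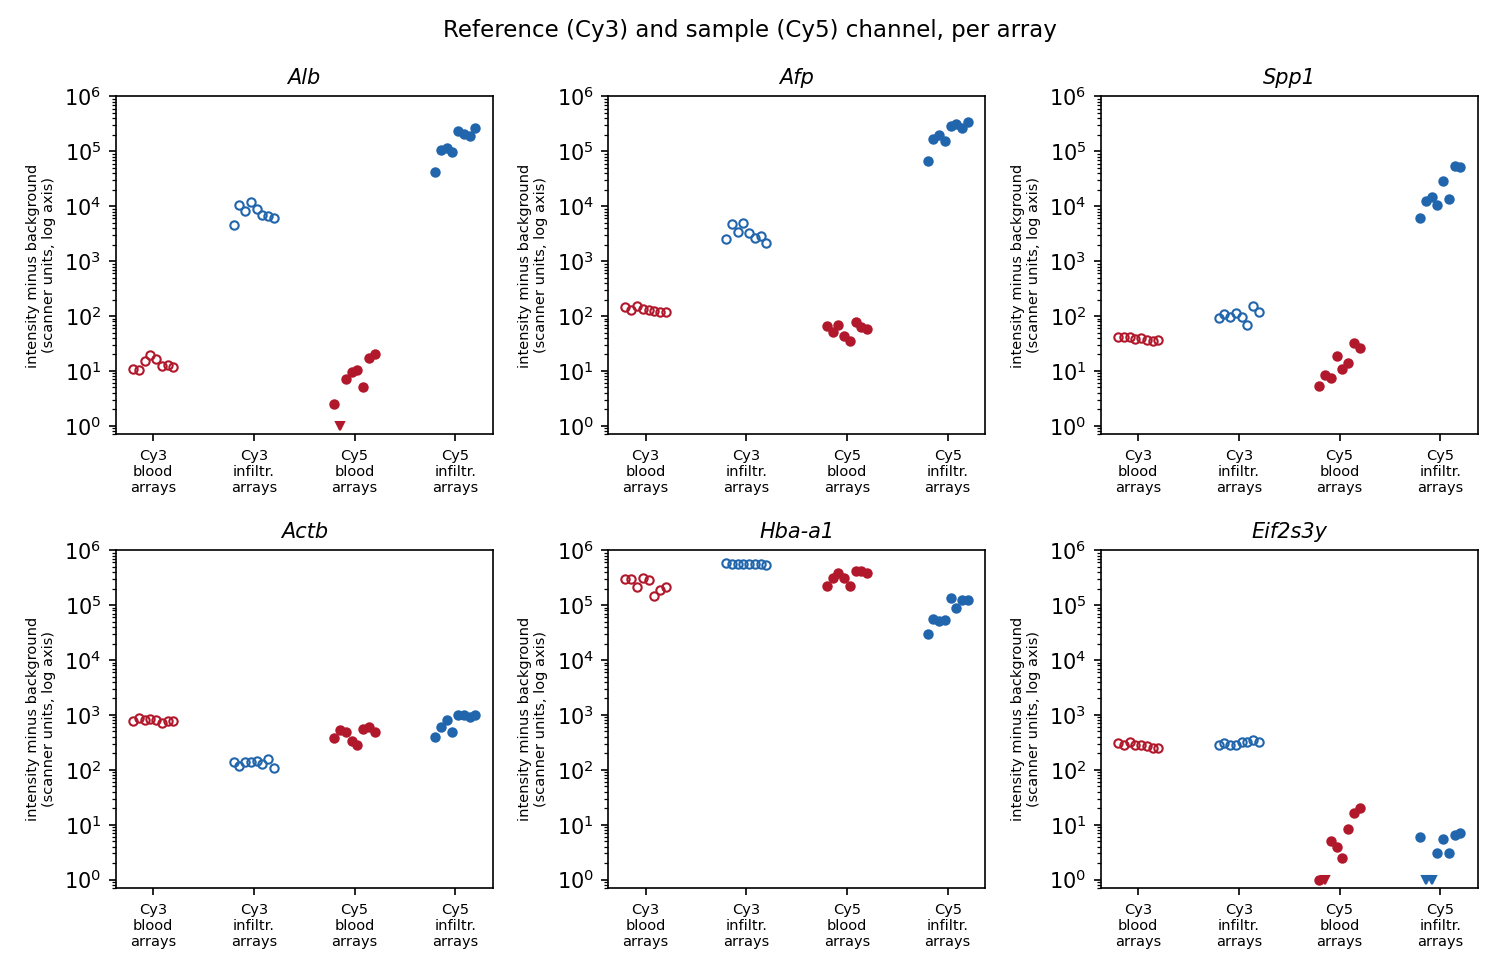
Background-subtracted intensity in scanner units (log axis) of 6 genes in the reference channel (Cy3, open) and the sample channel (Cy5, filled), 1 point per array, red for blood arrays and blue for infiltrating-cell arrays; triangles mark values below 1. Afp had 118 to 150 units in Cy3 of the blood arrays and 2171 to 4884 in Cy3 of the infiltrating-cell arrays.

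Median centring called 7711 genes, 7377 higher and 334 lower, spike-in centring 11575, 98.1% of them higher, and the deposited ratios 7006, 4232 higher and 2774 lower, against 50.6% higher among the 2935. Without infiltrating-cell arrays 897 and 898, 3382 genes were called, and the Cy5 channel alone called 4454, of which 2498 were shared with the 2935.

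Blood and infiltrating cells were also set side by side, to ask which changes against the reference they share. Genes called in both numbered 47, of which 22 moved alike and 25 in opposite directions. Higher in both were 9, including Cd82 (2.19 in blood, 1.17 in infiltrating cells), Adam8 (1.37 and 2.21), Dusp1 (1.27 and 2.68), Tbx21 (1.13 and 1.40) and Il1b (1.34 and 1.01). Lower in both were 13, among them Ms4a1 (−1.35 and −7.00), Cd79b (−1.54 and −5.60), Tnfrsf13c (−1.22 and −4.82) and Eif2s3y. Higher in blood and lower in infiltrating cells were 22, with Gabarapl2 (2.85 and −2.80), Isg15 (1.61 and −2.02), S100a8 (1.11 and −2.85) and Itga2b (1.45 and −3.53). Lower in blood and higher in infiltrating cells were 3, namely Ctss (−1.07 and 2.04), Klf4 (−1.01 and 1.74) and Ktn1 (−1.08 and 1.07). Leaving out 1 sample number ended a call of 7 of the 22 and of 8 of the 25. Among those named here these were Klf4 in blood without 890 (−0.98), 891 (−0.99), 894 (−0.98), 896 (−0.99) or 898 (−0.98), S100a8 in blood without 898 (0.995), and Il1b in infiltrating cells without 889 (0.94), 896 (0.996), 897 (0.94) or 898 (0.97). In infiltrating cells 2 of the 22 and 7 of the 25 changed sign with median centring, and 2 and 10 with spike-in centring. Both calls were kept with median and with spike-in centring by 1 and 2 of the 9 higher in both, 8 and 7 of the 13 lower in both, 1 and 0 of the 22 higher in blood and lower in infiltrating cells, and 3 and 3 of the 3 opposite to these. Of the genes named here, Adam8 (0.73 and 0.82), Dusp1 (0.62 and 0.72), Tbx21 (0.56 and 0.58), Il1b (0.70 and 0.79), S100a8 (0.54 and 0.56) and Itga2b (0.79 and 0.89) lost the call in blood with both, and Isg15 with median centring (0.97). In infiltrating cells Gabarapl2 (−0.64 and −0.94), Isg15 (−0.07 and −0.15) and S100a8 (−0.76 and −0.98) lost it with both. Independent lists of these sizes would share 5.78 higher and 3.04 lower genes. In 80 simulations of unchanged groups against a shared reference, a median of 6 and at most 27 genes were called alike. The simulated reference deviated like 1 blood sample and was identical for both groups. The measured reference channel differed between the sets of arrays, so this setting departs from the data. Mean ratios of the groups had a Pearson correlation of −0.26 across genes, which are not independent replicates, against a simulated median of 0.86 (0.33 to 0.96). Their covariance was −0.074, against a simulated median covariance of 0.028, a difference of −0.10. The reference is 1 sample and cannot be split, so the part of the alike calls that comes from the shared reference was not separated.

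**Figure D4:**
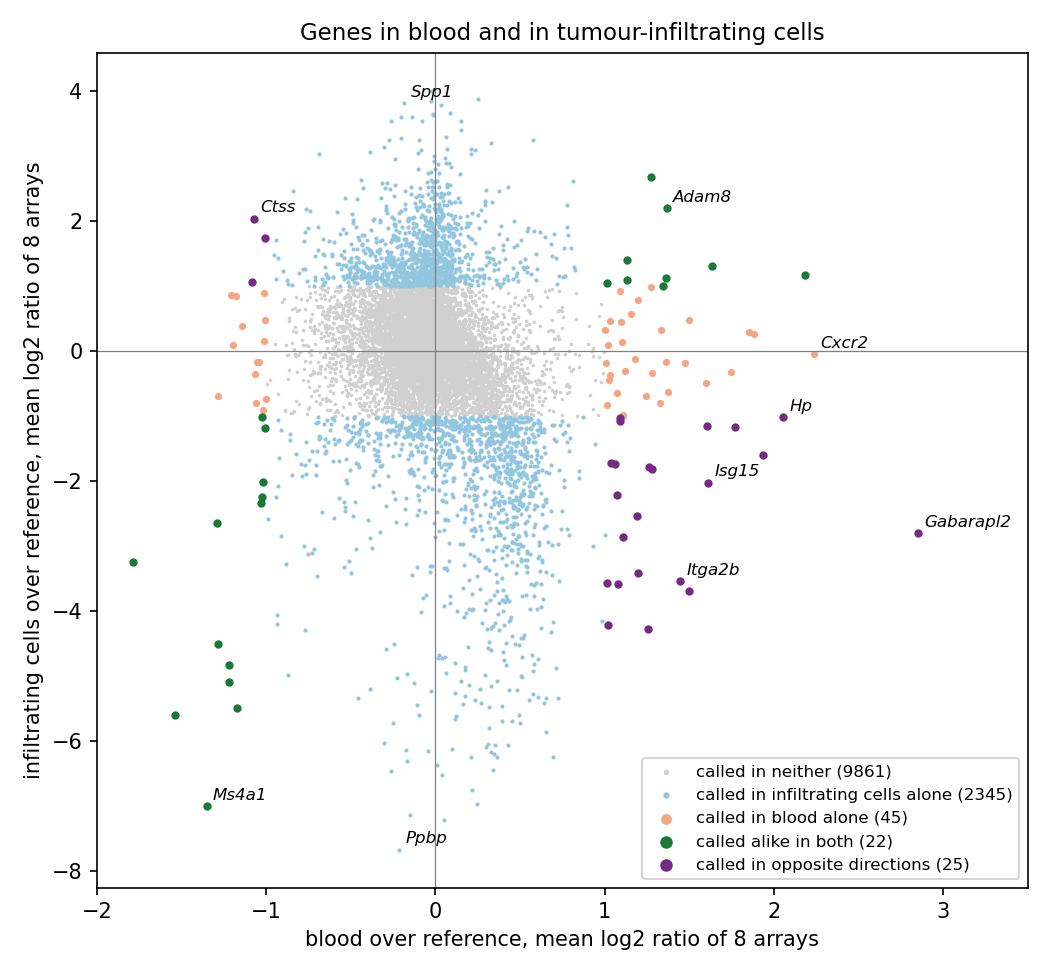
Mean log2 ratio over the reference of 12298 genes in blood (horizontal) and in infiltrating cells (vertical), 1 point per gene, coloured by the calls. The 22 genes called alike and the 25 called in opposite directions stand out from 2345 called in infiltrating cells alone and 45 in blood alone.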

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

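The tests on a missing thymus, on slides, on a fixed share of Cy5 signal, on liver or tumour transcripts in the reference and on probes bright in Cy3 whatever the gene were chosen only after the results were seen.

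Of 198 groups of 8 values examined for a single sample far from the others, 9 had one, and chance sets 1 sample apart in about 1 of 20 groups. In blood these included Scd2 in sample 896 (−1.02; nearest other −0.73) and Sparc in 894 (−0.55; −0.20). In infiltrating cells they were Arg1 in sample 893 (0.05; nearest other 0.57), Egr2 in 897 (1.62; 2.84), Pdcd1 in 897 (1.04; 1.52), Spp1 in 894 (4.26; 3.90), Tspan12 in 897 (2.69; 3.67) and the median of T cell genes in 896 (−1.24; −0.67). Sample 897 held 3 of these, each below its nearest other value. Its array's 10th percentile of corrected intensity was raised, at 561 units in Cy5 and 419 in Cy3, against 12.5 and 7.84 for sample 889. Chance and the background correction of that array were not told apart.

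Some genes were higher than the reference in blood and lower in infiltrating cells, with the difference itself tested and called with loess. The differences included −3.54 for Aldh2, −5.66 for Gabarapl2, −2.94 for Hdc, −3.07 for Hp, −3.63 for Isg15, −4.98 for Itga2b, −3.96 for S100a8 and −4.60 for Zbtb46. In infiltrating cells the values of Hdc (0.90 and 0.70), Hp (0.61 and 0.85) and Aldh2 (0.48 and 0.27) were above 0 with median and spike-in centring, and with median centring their differences were −0.22, −0.78 and −0.79. Gabarapl2 (−0.64 and −0.94), Isg15 (−0.07 and −0.15) and S100a8 (−0.76 and −0.98) lost their call in infiltrating cells with both. In blood Itga2b (0.79 and 0.89), S100a8 (0.54 and 0.56) and Zbtb46 (0.54 and 0.64) lost theirs with both, and Isg15 with median centring (0.97). Of the 22 genes of this kind 1 kept both calls with median centring and 0 with spike-in centring. The call of Hp in infiltrating cells (−1.01) was lost without sample 890 (−0.998), 891 (−0.97), 893 (−0.94) or 894 (−0.99), and that of S100a8 in blood (1.11) without 898 (0.995). Ctss, a protease of antigen-presenting cells, went the other way (3.12). The lists were erythroid genes (−4.98), neutrophil genes (−0.93) and platelet genes (−4.74), whose medians in blood were −0.08, −0.02 and −0.37 with spike-in centring. With an estimated correlation between genes these 3 differences were not called (camera adjusted p = 0.0943, 0.3 and 0.218, each the highest over 28 alternatives, with lowest values of 3.2e-64, 5.7e-05 and 6.9e-44), and the neutrophil difference was −0.06 with median centring and 1.49 with spike-in centring.

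Among 100 splits of the 16 arrays into 8 and 8, only 1, the real one, called as many genes, 2935 against at most 2244 in another split, which held 7 of 8 infiltrating-cell arrays on one side. For gene lists it was also 1 of 100, with 14 called against at most 12. However, splits with 4 infiltrating-cell arrays on each side called 0 genes, yet most of them called at least 1 list and 1 of them called 6. List calls at the preset correlation thus also arise without a contrast of the groups, and with an estimated correlation no list was called. A random split can be excluded as the whole source of the gene count, which shows that the sets of arrays differ but not why. For the list count the splits do not decide this. Slides, sample handling and RNA kits coincide with the groups, so a batch or handling effect stays open.

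The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were well above background in the reference channel of all 16 arrays and in no sample channel, although the labels give female for both. Probes bright in Cy3 whatever the gene stay open: the 8 such genes of 12298 include all 3 Y-linked genes tested (Fisher exact test, p = 1.81e-10), but these came into the tested set by their Cy3 signal alone, so the test restates the pattern. RNA of male mice in the reference may account for the signal: Xist, transcribed from the silenced X of females, had fitted ratios of 0.50 ± 0.07 in blood (positive on 7 of 8 arrays, above 96.0% of tested genes) and 1.71 ± 0.17 in infiltrating cells (8 of 8), which go with it, where more than 0.5 on 8 of 8 blood arrays was asked for. Xist was however not well above background in Cy3 on any blood array, so its ratio there is not exact and decides nothing. On the infiltrating-cell arrays Xist was well above background in Cy3 on 8 of 8 (43.5 to 66 units). That goes against RNA of male mice alone in that channel, but other genes of the reference channel also differed there. A signal of the Cy3 dye alone, at these probes or others, cannot be told apart from male RNA with 1 reference and no dye swap: Xist lay 6.99 standard errors above 0, past the bound of 2 set against it, but that bound was wrong, because 24.2% of tested genes lie that far above 0.

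T cell genes of blood lay near the reference, although the treatment text calls the mice athymic. Probes at background in both channels are argued against, since 78.9% of the 19 genes were well above background on all 8 blood arrays in both channels. A missing thymus in the tumour mice alone called for a median under −1, against −0.09 measured, −0.22 over the 15 genes above background, −0.66 with median centring and −0.64 with spike-in centring. Array medians ran from −0.21 to −0.06. Whether the strain field or the treatment text holds for these mice stays open, and so does a reference from mice that also lacked a thymus, which was not tested.

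The reference channel, not used by itself in the comparisons, differed at least 2-fold between the blood arrays and the infiltrating-cell arrays at 1208 probes, 903 higher and 305 lower on the latter. Variation of the size seen between slides of one set is argued against as the cause, since these differed at no more than 1.74% as many probes (21 and 17). Each set had its own slides, so this comparison cannot address a batch effect between the sets, which stays open. A fixed share of Cy5 signal read in Cy3 is argued against too, since that share ran from 0.516% to 8.27% (10th to 90th percentile of 130 probes), a ratio of 16. Liver or tumour transcripts in the reference RNA could be present: hepatoma and hepatocyte genes had a median Cy3 difference of 0.20, above the −0.20 to 0.10 of random sets but below the 0.5 that was asked for, with 7 of 15 genes at least 2-fold higher and 0 lower. Single members of that list differed far more than its median, by 6.31 log2 for Alb, 5.76 for Rbp4 and 3.46 for Afp. Arg1, of another list, differed by 3.90. Among infiltrating-cell arrays the SD of log2 Cy3 was 0.37 for Alb, 0.25 for Rbp4, 0.33 for Afp and 0.66 for Arg1. It was 0.12 for Eif2s3y, and the cause of this spread was not tested. Liver or tumour transcripts in the reference and a different preparation of the reference cannot be told apart, and no biological explanation was tested.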

How the results depend on the processing

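The alternatives chosen after seeing the data were normexp without debris spots, a maximum likelihood fit, subtraction with a floor, infiltrating-cell arrays 897 and 898 left out and spike-in centring. Calls rest mostly on the fold limit, so settings that leave log2 values alone keep the counts by construction: Aquantile scaling, slide as a random block, and intensity trend with robust moderation left all 222 named genes and lists on their side of the threshold. The labels do not say that samples of one number share a mouse. Their residuals correlated at −0.17 to 0.20, not all over 0.1, and 5 of 8 blood samples (6 of 8 without debris spots) correlated best with their own number. Each number also held the same position on its slide in both groups, so pairing and array position cannot be told apart. The replicate block gave 2935 genes again. Without each sample number in turn, blood called at fewest 75 genes and at most, without 889, 68 higher and 37 lower, infiltrating cells 2312 to 2625 and their difference 2832 to 3145, with 16 to 24 alike, 33 to 39 lists and 133 to 136 named genes. Without debris spots the 3 counts were 97, 2843 and 3393, with the maximum likelihood fit 93, 2391 and 2937, with subtraction and a floor 100, 2824 and 3392, and without arrays 897 and 898 they were 92, 2823 and 3382. Counts that moved by over 1.5 times follow. No background correction called 53 genes in blood and 13 alike. The deposited ratios and the series' value table, which hold the same values, called 956, 5759 and 7006 genes and 167 alike. Median centring called 894, 7260 and 7711, and spike-in centring 673, 11087 and 11575; the shift of the centre, printed above, is the part of the cause that the tables show. Adjusted p alone called 6126, 9395 and 9212 genes and 1515 alike, a 1.5-fold limit 622, 4486 and 5144 and 145 alike, and a 4-fold limit 4, 658 and 833 and 0 alike, by construction. With fewer samples, the first slides called 61 genes in blood and 14 alike, and the second slides 152 and 36. With fewer genes, those well above background in both channels on all 16 arrays, 20 lists were called in place of 37. With an estimated correlation between genes camera called 0 of 69 list tests, 12 of which had an unadjusted p under 0.05. Cy5 alone called 4454 genes different between the groups. Reversed with median centring were H2-Ab1 (0.56), Hdc (0.90) and Csf1r (2.002) in infiltrating cells against the reference, and Ccr7 (0.28), H2-Oa (0.0916), Esam (0.96), Cd3e (0.17), Il1b (2.44) and T cell genes (1.46) against blood. Reversed with spike-in centring were Lef1 (0.21), H2-Ab1 (0.19), Hdc (0.70), Cd3e (1.12), Ncr1 (1.75) and Csf1r (1.82) against the reference, and Ccr7 (0.37), Lef1 (0.82), H2-Oa (0.0485), H2-DMb2 (1.06), Esam (1.23), Il27 (1.38), Eif2s3y (0.96), Ddx3y (1.20), Cd3e (1.23), Ncr1 (2.40) and Il1b (2.08) against blood. For the other changes the cause was not tested. A further 23 values of 9 named results, called under neither setting, crossed 0. Of the 222, 162 kept direction and side of the threshold with median centring, 175 with spike-in centring, 204 with the deposited ratios and 208 without background correction. The normexp variant of the rma method was not run. Signal over background limits genes dim in blood, whose Cy5 differences are bounds.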

Other observations

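No test reported in this part was added to those above. The other genes seen in the reference channel of all 16 arrays and in no sample channel were Blk, a kinase of B cells, Cldn10, Crct1, Galnt14 and Ppm1e. Kdm5d, the Y-linked gene that was not called, is given no ratio, since its Cy5 signal was not well above background on any array.

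In the reference channel alone, hypoxia and glycolysis genes had a median of 0.68 log2 on infiltrating-cell arrays over blood arrays, with 10 of 24 at least 2-fold higher. Immediate-early and heat-shock genes had 0.81 (7 of 22), chemokine genes 0.36 (6 of 20) and monocyte and macrophage genes 0.21 (7 of 21), while platelet genes had −0.56 and B cell genes −0.52. After scaling between arrays Actb, cytoskeletal actin, had −2.68 in the reference channel and −2.81 in the sample channel. Unscaled, its Cy3 signal was 720 to 885 units on blood arrays and 106 to 159 on infiltrating-cell arrays, but its Cy5 signal was 289 to 594 and 397 to 1012. The median Cy5 signal over all probes was 9 to 23 units on blood arrays and 24 to 95 on infiltrating-cell arrays. The fall of Actb in the sample channel is thus relative to the other probes of each array. Of 4454 genes at least 2-fold different in Cy5 alone, 635 differed at least 2-fold the same way in the reference channel.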
